A study of Homo sapiens with 12 samples.

How the data were processed

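RNA from 12 samples labelled as SKBR-3 was measured on Illumina expression arrays. The labels divide the samples into 6 groups of 2: untreated, Y15 at 1 µM, PF04554878 at 1 µM, lapatinib at 5 µM, and lapatinib at 5 µM together with either Y15 or PF04554878 at 1 µM. Treatment lasted 24 hours per the series' design text. Total RNA was extracted with TRIZOL and copied into biotin-labelled cRNA per the labels' protocols. The extraction protocol speaks of frozen tissue, although the samples are labelled as a cell line. The labels name no vehicle for the untreated samples and do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

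The values used are the log2 probe intensities that the authors deposited as a processed table. GenomeStudio is named in the submitters' processing notes, without a version, and the background handling and normalization are not given in the sources used here. The values themselves ran from 6.20 to 13.90 on the log2 scale, and the sorted columns of the 12 arrays differed by at most 0.0146, as quantile normalization leaves them. The mode of all values lay at 6.55, far from 0. Whether background was left in or an offset was added after a subtraction is not known. Folds on such a scale are compressed, most of all for dim genes. The planned starting point had been a second deposited table of raw signals with detection p-values. Its 24 per-sample columns carry names that match no sample's label, so they were not used, and the planned background correction and detection filter were replaced by the steps below.

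Background was described by the mode of all values and the SD around it of the values below it, 0.0827. A probe counted as above background where it exceeded the mode by 3 SD, a cutoff of 6.80. Of 47318 probes, 30111 carried 1 gene symbol in the platform annotation, 8 carried several and 17199 carried none. Updating symbols through gene numbers changed 0 of them. Probes above the cutoff on at least 2 of the 12 arrays were kept, 19922 in all, and each gene was represented by its kept probe with the highest mean over the 12 arrays, which gave 11564 genes. Where all probes of a gene lay below the cutoff on both arrays of a group, the fold is given as a lower bound, the brighter group's mean against the cutoff. For interactions such a group was set at the cutoff where this bounds the size, and otherwise no bound is given. About 34.4% of probes lay above the cutoff on each array. Of 2015 called genes with further kept probes in lapatinib against untreated, 50 had a called probe of the opposite sign. The number of arrays limits the precision.

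Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 12 arrays, which left 6 residual degrees of freedom plus 9.10 from the prior. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. There were 11 comparisons chosen before the data were examined. A further 2, which set each combination against its FAK inhibitor alone, were added after seeing the data. Interactions were tested as combination minus FAK inhibitor minus lapatinib plus untreated. Shifts of 26 gene lists, written before the data were examined, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, and repeated with an estimated correlation. The repeat gave larger p-values even for some lists whose estimated correlation lay below 0.01. A call lost in it does not by itself show correlated members. Another 5 lists held markers of other cell types.

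Genes were named by a rule fixed before the data were examined: the 8 largest increases and 8 largest decreases past the threshold in each comparison against untreated, with no overlap between the replicates of the groups, 4 each way in the other comparisons, the 4 members with the smallest adjusted p of each list that passed, and PTK2, PTK2B, EGFR, ERBB2 and ERBB3 in every comparison. Only part of the values of these 5 genes is printed, chosen after they had been seen. ACTA2 and CDH3 beside the luminal lists were also named after their values had been seen, and these values were not refitted under the alternatives. ESR1, PGR, GREB1 and GRB7 were looked up after the data had been seen. The fit was tested on simulated data for Y15 against untreated over 11564 genes, in which 200 genes were changed. It called 72.0% of the 50 genes raised by 0.5 log2 units, 92.0% of those raised by 1, 100% of those raised by 2 and 60.0% of those lowered by 0.5, and 11 of 11364 unchanged genes. The simulated noise of a gene had the same spread in every group. In the data the untreated arrays differed with an SD of 0.229 across genes, against 0.140 for Y15, so these rates may not hold there.

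Alternatives were no filter on dim probes, a filter on all 12 arrays, every probe as a feature, a fit of the compared groups only, the replicate number as a block, and each sample left out in turn. Subtraction of the background mode and a variance trend were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.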

Results

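Expression was profiled in 12 samples labelled as SKBR-3, a breast cancer line known for ERBB2 amplification and for lacking the oestrogen receptor. The series set inhibitors of focal adhesion kinase (FAK, encoded by PTK2) beside lapatinib, a kinase inhibitor of EGFR and ERBB2 (HER2), alone and combined. Y15 and PF04554878 (defactinib) are both FAK inhibitors. Each of the 6 groups held 2 arrays, and between 9648 and 9877 of the 11564 genes tested lay above background on each. Values are log2 intensities, and errors are standard errors of the fit unless given as SD.

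The arrays fell into 3 sets that crossed the treatment labels. Replicates of a group correlated across genes with r from 0.987 to 0.995. The untreated arrays correlated almost as highly with those labelled Y15 (mean r 0.986), those labelled lapatinib with Y15 plus lapatinib (0.985), and those labelled PF04554878 with PF04554878 plus lapatinib (0.985). Between the sets, mean r ran from 0.875 to 0.937. Genes are not independent replicates, so these values describe the arrays only. The first 2 principal components, with 59.9% and 27.1% of the variance, separated the sets. In the untreated group, 1 of 2 arrays correlated best with an array outside its own group.

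**Figure D1:**
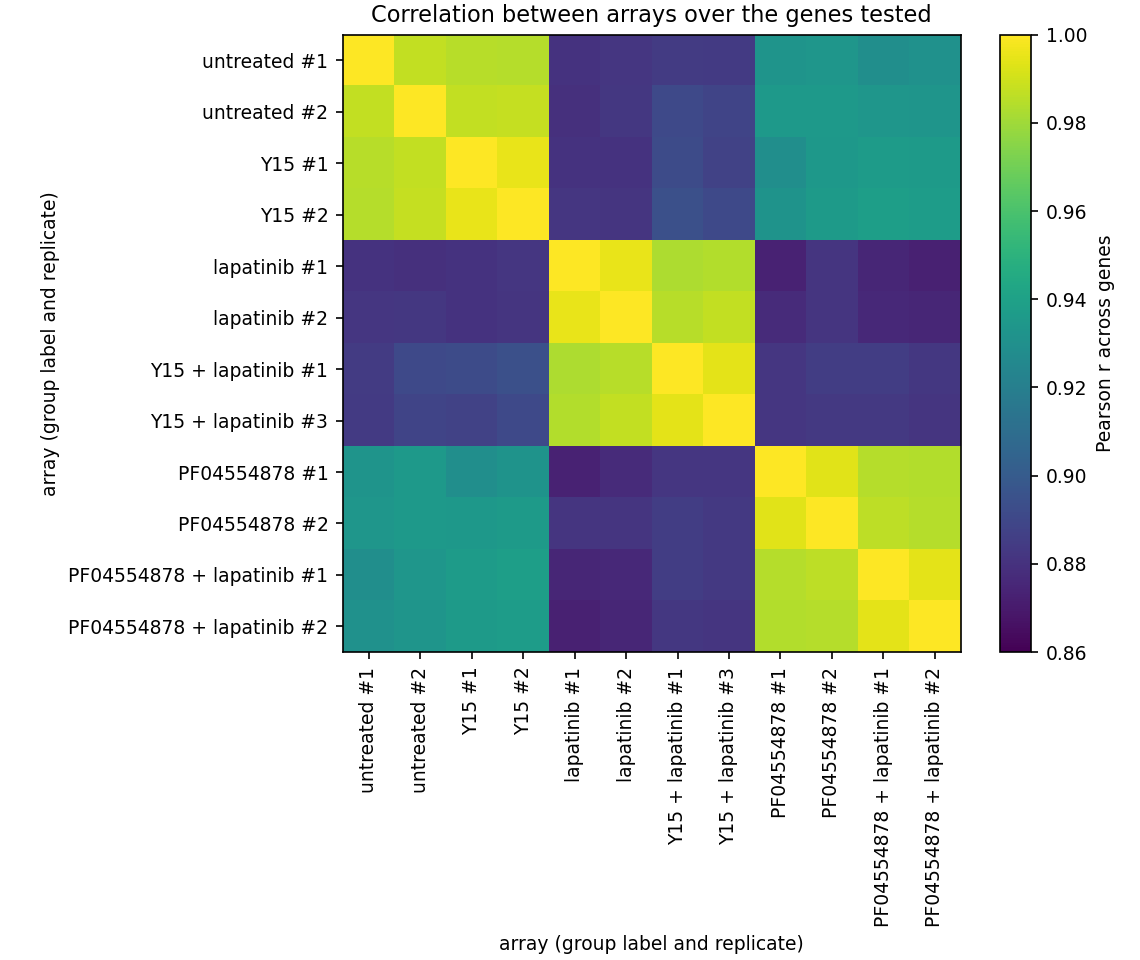
Pearson r across the 11564 genes for each pair of the 12 arrays, with group label and replicate on both axes and r as colour. The 3 blocks along the diagonal join groups with mean r of 0.985 or 0.986, while pairs of groups from different blocks have mean r between 0.875 and 0.937.

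The drug targets and receptor genes were read first, as a check on the labels. ERBB2 stood at 9.35 in the untreated arrays and at 8.50 in those labelled lapatinib on its brightest probe, while its other 2 probes were above background on 0 of the 12 arrays. Values of PTK2 below are also those of its brightest probe. A dimmer PTK2 probe, above background on all 12 arrays, had group means only from 6.92 to 7.24. ESR1, the oestrogen receptor, was above background on all 12 arrays, with group means from 9.85 to 10.44. TFF1, an oestrogen-regulated gene, stood at 12.63 in the untreated arrays and at 6.48, below background, in those labelled lapatinib. PGR, the progesterone receptor, stood at 7.83 and 10.55 in the same groups. The ESR1 levels go against the cell line named in the labels, so the samples are called "the arrays labelled" by their group throughout, and every direction below is drawn from those labels.

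**Figure D2:**
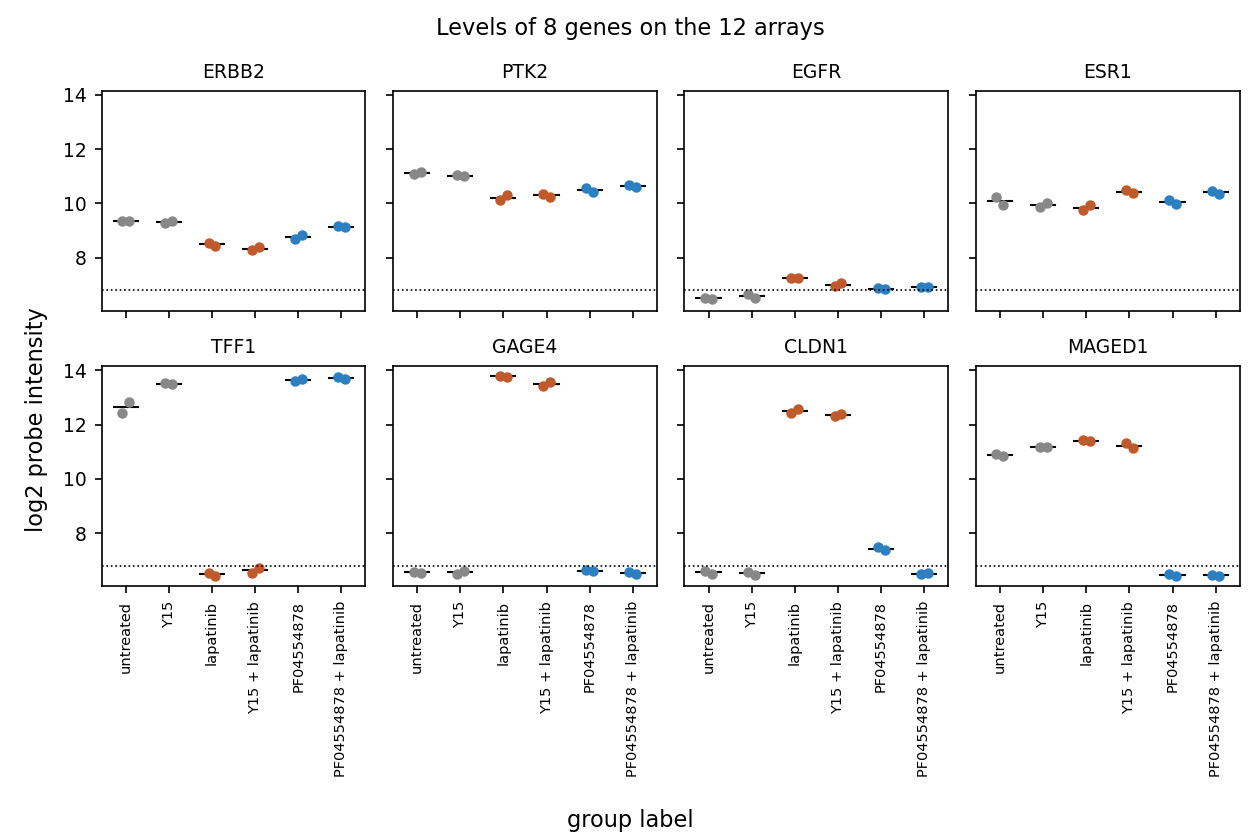
Log2 probe intensity (y axis) of 8 genes on each array, by group label (x axis), with points for the 2 arrays, bars for their mean and a dotted line at the background cutoff of 6.80. ESR1 lies above the cutoff on all 12 arrays, TFF1 is at 6.48 in the group labelled lapatinib, and GAGE4 and CLDN1 are high in the groups labelled lapatinib and Y15 plus lapatinib.

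Of the markers of other cell types on the array, 3 of 13 fibroblast, 1 of 10 endothelial and 1 of 14 leukocyte markers passed the filter. So did 3 of 8 basal epithelial and 2 of 9 adipocyte markers. The 3 basal markers were above background on both arrays of every group. Of the fibroblast markers 3 passed the filter, with COL5A1 highest at 8.86 in the arrays labelled PF04554878 and 7.33 in the untreated arrays. Single endothelial and leukocyte markers passed, ESAM at up to 7.25 and CD68 at up to 8.21. The 3 basal epithelial markers that passed included ACTA2, at 7.12 in the untreated arrays, 7.27 in those labelled Y15, 9.36 with lapatinib, 8.79 with Y15 plus lapatinib, 8.87 with PF04554878 and 8.81 with PF04554878 plus lapatinib, and CDH3, at 8.56, 8.94, 8.54, 8.57, 8.79 and 9.04 in the same order of groups. Of the adipocyte markers 2 passed, with LEP highest at 8.46 in the arrays labelled Y15.

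The first comparison asks what the FAK inhibitor Y15 does alone. The arrays labelled Y15 had higher TFF3, an epithelial trefoil peptide (3.64-fold, log2 change 1.86 ± 0.13, adjusted p = 2.52e-06), PODXL, a surface sialomucin (1.42 ± 0.10), and IER3, an immediate early gene (1.15 ± 0.12). H19, TH, HEY2, XBP1 and GDF15 rose by between 0.99 and 1.12. KITLG, the KIT ligand, fell by 1.40 ± 0.17 and EFEMP1, an extracellular matrix gene, by 1.20 ± 0.24, followed by SOWAHA, ANAPC13, SSRP1, ENTREP3, MORF4L1 and GDAP1, with log2 changes from -1.03 to -0.86. PTK2 itself differed by -0.10 ± 0.10 (adjusted p = 0.605) and ERBB2 by -0.03 ± 0.09 (adjusted p = 0.897). By limma, 629 of 11564 genes passed, 340 higher and 289 lower, and 9 of them changed at least 2-fold. This count may be too high, since the fit pools the spread of all groups. The 2 untreated arrays differed with an SD of 0.229 across genes, against 0.140 for those labelled Y15.

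Of the 26 lists, 5 passed camera for Y15 against untreated, each with its call lost in the repeat with an estimated correlation. That estimate was below the preset 0.01 for the luminal (-0.00375) and metallothionein (-0.0578) lists. It was above 0.01 for ERK pathway output (0.0524), FOXO targets (0.0377) and ribosome biogenesis (0.0119). In the ERK pathway output list, 4 of 22 measured members rose and 1 fell, the same numbers when adjusted over the list alone, with IER3, DUSP5 (0.81 ± 0.11) and EGR1 (0.52 ± 0.10) among them (adjusted p = 0.00505, and adjusted p = 0.226 with an estimated correlation). Among FOXO targets, 2 of 24 rose and 1 fell, against 5 and 1 adjusted over the list alone, including YPEL3 (0.59 ± 0.10) and FBXO32 (0.57 ± 0.11) (adjusted p = 0.00274, and adjusted p = 0.226 with an estimated correlation). In the luminal epithelial list 4 of 24 rose, or 6 adjusted over the list alone: TFF3, XBP1, TFF1 (0.87 ± 0.12) and TFAP2A (0.40 ± 0.10), with adjusted p = 0.00178 and adjusted p = 0.0925 with an estimated correlation. The basal epithelial markers CDH3 and ACTA2 differed by 0.38 ± 0.12 (adjusted p = 0.0855) and 0.15 ± 0.09 (adjusted p = 0.369). Of 11 genes for metallothioneins and zinc transport, 3 fell, or 6 adjusted over the list alone, namely MT1F (-0.83 ± 0.10), MT1X (-0.80 ± 0.15) and MT2A (-0.53 ± 0.15), while the zinc importer SLC39A4 rose (adjusted p = 0.00178, and adjusted p = 0.0925 with an estimated correlation). Ribosome biogenesis genes shifted down with 2 of 27 called, WDR12 and TSR1, and the same 2 adjusted over the list alone (adjusted p = 0.0448, and adjusted p = 0.226 with an estimated correlation). The count moved to 60 in a fit of these 2 groups alone, to 192 after background subtraction, to 147 and 136 without Y15 replicate 1 or 2, and to 1171 without untreated replicate 2. The calls of EFEMP1, GDAP1, EGR1, TFAP2A, MT2A, WDR12 and TSR1 ended without either Y15 array, those of YPEL3, FBXO32 and SLC39A4 without replicate 1, and that of MT1X without replicate 2.

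**Figure D3:**
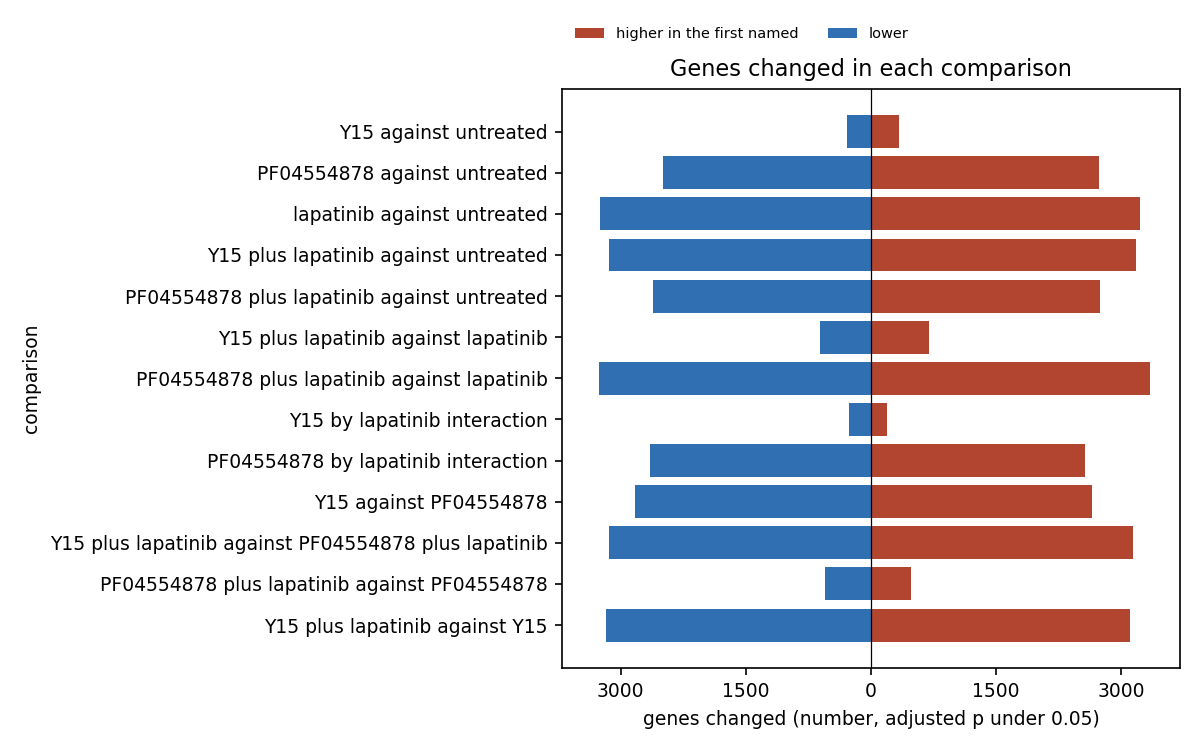
Number of genes with adjusted p under 0.05 in each comparison (y axis), drawn to the right where higher in the first named group or with a positive interaction, and to the left where lower. Counts are 629, 1306, 447 and 1027 where both groups lie in the same set or for the Y15 interaction, and between 5208 and 6612 elsewhere.

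The arrays labelled PF04554878 differed far more from untreated. UBB, a ubiquitin gene, was 15.1-fold higher (3.92 ± 0.17, adjusted p = 1.2e-10), LAMP3 3.48 ± 0.10 and the growth factor MDK 3.11 ± 0.09. PCDHB2, a protocadherin below background in the untreated arrays, was at least 8.97-fold higher, and HSPA1A, CPE, TFF3 and OAT rose by between 2.84 and 3.11. MAGED1 and TRIP6 were below background in the arrays labelled PF04554878, at least 17-fold and 17.9-fold lower, and KDELR1, an ER retention receptor, was at least 10.6-fold lower. SNAR-A1, PLS3, HBA2, CEP20 and IGFBP5 fell, with log2 changes from -3.87 to -2.57. PTK2 fell by 0.62 ± 0.10 and ERBB2 by 0.59 ± 0.09 on their brightest probes. A dimmer PTK2 probe stood at 7.24 in the untreated arrays and 7.17 in those labelled PF04554878. In total 5232 genes passed, 2735 higher and 2497 lower, 624 of them by at least 2-fold. Ribosome biogenesis genes fell in 18 of 27 cases, or 19 adjusted over the list alone, and rose in 2, with NHP2 (-1.40 ± 0.09) and NOP16 (-1.15 ± 0.11) among the falls (adjusted p = 4.51e-05, and adjusted p = 0.0869 with an estimated correlation). Of 24 luminal epithelial genes, 13 rose and 2 fell, the same adjusted over the list alone, led by TFF3 (2.98 ± 0.13), AGR2 (2.05 ± 0.14), CDH1 (1.93 ± 0.11) and XBP1 (1.39 ± 0.10), with adjusted p = 0.0118 and adjusted p = 0.134 with an estimated correlation. The basal epithelial marker ACTA2 was higher in the same arrays, by 1.75 ± 0.09, and CDH3, another, differed by 0.23 ± 0.12 (adjusted p = 0.149).

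For lapatinib alone, the largest rises were in GAGE genes, cancer-testis antigens normally silent outside the germ line. GAGE4 was at least 126-fold higher in the arrays labelled lapatinib (adjusted p = 1.17e-17) and GAGE12G at least 110-fold. These probes belong to near-identical paralogs, so the member is uncertain. CLDN1, a tight junction gene, was at least 52.2-fold higher. TFF1 was at least 56.9-fold lower, BASP1 at least 20.7-fold, HENMT1 at least 13.9-fold, SYTL2 at least 12.3-fold and ME1 at least 8.31-fold, while HBA2 (-3.63 ± 0.15), BCL2 and GFRA1 (-3.37 ± 0.11) fell too. PTK2 fell by 0.91 ± 0.10 and ERBB2 by 0.85 ± 0.09, whereas EGFR, below background in the untreated arrays, was at least 1.37-fold higher. The EGFR rise rests on a dim probe, at 6.51 in the untreated arrays and 7.25 with lapatinib. Its other probes stood at 6.71, 6.63 and 6.60 in the untreated arrays and at 6.78, 6.60 and 6.49 with lapatinib. ERBB3 rose by 0.46 ± 0.14, a call that ended without untreated replicate 1 or lapatinib replicate 1. A total of 6470 genes passed, 3229 higher and 3241 lower, with 1262 changed at least 2-fold.

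Antigen presentation genes rose in 11 of 17 cases for lapatinib against untreated and fell in 1, the same adjusted over the list alone, including HLA-B (at least 12.1-fold), PSMB8 and TAP1 (1.48 ± 0.13), with adjusted p = 0.00466 and adjusted p = 0.178 with an estimated correlation. Of 23 YAP and SRF targets, many of which encode cytoskeletal or contractile proteins, 12 rose and 4 fell, or 5 fell adjusted over the list alone, with FHL2 (3.07 ± 0.16) and ACTA2 (2.24 ± 0.09) among the rises (adjusted p = 0.0285, and adjusted p = 0.280 with an estimated correlation). NRF2 targets fell in 10 of 19 cases and rose in 2, the same adjusted over the list alone, including AKR1C2 and FTL (-1.41 ± 0.11), with adjusted p = 0.0445 and adjusted p = 0.280 with an estimated correlation. Of 11 genes for metallothioneins and zinc transport, 8 fell and 1 rose, the same adjusted over the list alone, including MT1F (-2.37 ± 0.10) and SLC39A6 (-3.09 ± 0.17), with adjusted p = 0.0278 and adjusted p = 0.236 with an estimated correlation. ACTA2 is also a basal epithelial marker.

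The arrays labelled Y15 plus lapatinib, against untreated, showed nearly the profile of those labelled lapatinib. GAGE4 was at least 103-fold higher, GAGE12H at least 91.7-fold and CLDN1 at least 46.8-fold, and TFF1 was at least 56.9-fold and HENMT1 at least 13.9-fold lower. LCP1 fell by 3.37 ± 0.08 and SLC39A6 by 3.34 ± 0.17. ERBB2 fell by 1.01 ± 0.09, PTK2 fell by 0.81 ± 0.10 and ERBB3 rose by 0.69 ± 0.14. Of 6309 genes that passed, 3171 were higher and 3138 lower. Antigen presentation genes rose in 10 of 17 cases and fell in 1 (adjusted p = 0.0115, and adjusted p = 0.204 with an estimated correlation), and metallothionein and zinc transport genes fell in 8 of 11 and rose in 1 (adjusted p = 0.0192, and adjusted p = 0.204 with an estimated correlation), each the same adjusted over the list alone. Fold changes of this comparison and of lapatinib against untreated correlated across genes with r = 0.943 and had a covariance of 0.434. Simulated unchanged groups that share the untreated arrays gave 0.499 and 0.00687. The simulation gave every group the same spread, although the untreated arrays varied more, so its values may be too low. Both called 2593 genes higher, against 885 for independent lists, and 2611 lower, against 879. Part of the excess may come from the 2 shared untreated arrays, which were not split, since each comparison would have kept 1.

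The arrays labelled PF04554878 plus lapatinib, against untreated, in turn resembled those labelled PF04554878. UBB rose by 3.96 ± 0.17 and MDK by 3.46 ± 0.09, and ELOVL2, a fatty acid elongase, was at least 10.1-fold higher. MAGED1 was at least 17-fold and TRIP6 at least 17.9-fold lower. GAGE4 and CLDN1 were below background here. Across genes, fold changes correlated with those of PF04554878 against untreated at r = 0.901 with a covariance of 0.232, and with those of lapatinib against untreated at r = 0.325 with a covariance of 0.115, against 0.499 and 0.00687 simulated for unchanged groups. With PF04554878 against untreated, 2134 genes were called higher in both (648 for independent lists) and 1987 lower in both (564). With lapatinib against untreated, 1232 were called higher in both (765) and 1355 lower in both (733), while 924 were called opposite ways. Part of each excess may come from the shared untreated arrays. PTK2 fell by 0.47 ± 0.10, and ERBB2 differed by -0.20 ± 0.09 (adjusted p = 0.0945). In all, 5353 genes passed, 2739 higher and 2614 lower. The luminal epithelial list shifted up with 16 of 24 members rising and 3 falling, or 17 rising adjusted over the list alone (adjusted p = 0.000165, and adjusted p = 0.0480 with an estimated correlation), with CDH1 (2.19 ± 0.11) and SPDEF (1.46 ± 0.10) among them, and the basal epithelial markers ACTA2 and CDH3 rose by 1.69 ± 0.09 and 0.48 ± 0.12. Ribosome biogenesis genes fell in 15 of 27 cases and rose in 2, or 17 falls adjusted over the list alone (adjusted p = 7.3e-05, and adjusted p = 0.0480 with an estimated correlation), including NHP2 and POLR1C (-1.41 ± 0.12). The p53 targets rose in 10 of 19 cases and fell in 1, the same adjusted over the list alone, with CDKN1A, a cyclin-dependent kinase inhibitor, at 1.88 ± 0.19 (adjusted p = 0.0295, and adjusted p = 0.187 with an estimated correlation). Of 30 mitotic genes 16 fell, including BIRC5 (-1.21 ± 0.10) and CCNB2 (-0.75 ± 0.10), and 3 rose, including CDK1 (0.68 ± 0.09), the same adjusted over the list alone (adjusted p = 0.0197, and adjusted p = 0.282 with an estimated correlation).

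The arrays labelled Y15 plus lapatinib were then set against those labelled lapatinib. IER3 rose by 1.53 ± 0.12, the homeobox genes HOXC8 and HOXC9 by 1.22 ± 0.11 and 1.20 ± 0.10, and CTDSPL by 1.12 ± 0.09. DKK1, a Wnt antagonist, fell by 1.87 ± 0.12, APP by 1.53 ± 0.20 and SSRP1 by 1.51 ± 0.11. In all 1306 genes passed, 699 higher and 607 lower, 16 of them by at least 2-fold. Mitotic genes shifted up, with 8 of 30 rising and 1 falling, or 15 and 1 adjusted over the list alone, led by CENPE (0.94 ± 0.11), while BIRC5, an inhibitor of apoptosis, fell by 0.63 ± 0.10, with adjusted p = 1.7e-06 and adjusted p = 0.104 with an estimated correlation. DNA replication genes rose in 5 of 29 cases, or 7 adjusted over the list alone, including MCM10 (0.83 ± 0.10), with adjusted p = 0.00257 and adjusted p = 0.179 with an estimated correlation. The ATF4 and amino acid list shifted down with 9 of 29 falling and 2 rising, or 13 and 3 adjusted over the list alone, where ASNS, asparagine synthetase, fell by 1.11 ± 0.10 and the amino acid transporter SLC7A5 rose by 0.77 ± 0.11 (adjusted p = 0.00057, and adjusted p = 0.208 with an estimated correlation). Ribosome biogenesis genes rose in 8 of 27 cases, the same adjusted over the list alone (adjusted p = 0.00718, and adjusted p = 0.174 with an estimated correlation). Heat shock genes rose in 5 of 19 and fell in 1, or 7 and 1 adjusted over the list alone (adjusted p = 0.0213, and adjusted p = 0.208 with an estimated correlation), and xenobiotic genes rose in 4 of 9, or 6 adjusted over the list alone (adjusted p = 0.000668, and adjusted p = 0.130 with an estimated correlation). The count was 299 and 542 without lapatinib replicate 1 or 2, 504 and 620 without Y15 plus lapatinib replicate 1 or 3, and 513 after background subtraction.

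PF04554878 plus lapatinib against lapatinib set groups of different sets against each other. TFF1 was at least 122-fold higher in the arrays labelled with the combination, BASP1 at least 59.5-fold, SERPINA3 at least 25.7-fold and HENMT1 at least 22.2-fold. GAGE4 was at least 126-fold and GAGE12J at least 117-fold lower. Of 6612 genes that passed, 3349 were higher and 3263 lower. The p53 targets rose in 14 of 19 cases, or 16 adjusted over the list alone, and 1 fell: CDKN1A rose by 3.02 ± 0.19 and TP53I3 fell by 4.05 ± 0.09 (adjusted p = 0.00763, and adjusted p = 0.146 with an estimated correlation). NRF2 targets rose in 9 of 19 cases and fell in 1 (adjusted p = 0.0148, and adjusted p = 0.233 with an estimated correlation), antigen presentation genes fell in 10 of 17 and rose in 1 (adjusted p = 0.0104, and adjusted p = 0.146 with an estimated correlation), and YAP and SRF targets fell in 12 of 23 and rose in 2 (adjusted p = 0.0148, and adjusted p = 0.233 with an estimated correlation), each the same adjusted over the list alone. Mitotic genes fell in 16 of 30 cases and rose in 3, or 17 and 4 adjusted over the list alone (adjusted p = 0.0194, and adjusted p = 0.268 with an estimated correlation).

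The interactions asked, by the labels, whether the effect of a FAK inhibitor differed beside lapatinib. For either inhibitor the 4 groups span different sets of arrays. For Y15, the groups with and without it lie within a set, so a constant log2 difference between sets cancels. A Y15 effect that differs between the sets cannot be told apart from a joint drug effect. For PF04554878, lapatinib against untreated crosses sets while the other difference does not. A difference between sets therefore enters that interaction directly and cannot be told apart from a joint drug effect. For Y15, TFF3 changed by -2.43 ± 0.18 relative to the sum of the single effects (adjusted p = 7.98e-06), EEF1A2 by -1.47 ± 0.20 and HEY2 by -1.32 ± 0.16, while SOWAHA changed by 1.31 ± 0.19 and PLK2, a p53-regulated kinase, by 1.23 ± 0.15. In all 447 genes passed, 189 positive and 258 negative. The count was 999 without untreated replicate 1, 30 and 194 without lapatinib replicate 1 or 2, 60 and 112 without Y15 replicate 1 or 2, and 176 and 131 without Y15 plus lapatinib replicate 1 or 3. It was 288 in a fit of the 4 groups alone and 5 after background subtraction, namely TFF3, HEY2, PLK2, DKK1 and FAM20C, of which DKK1 and FAM20C were named after their values were seen. For PF04554878, 5208 genes passed, 2561 positive and 2647 negative, with bounds, where a group lay below background, of at least 5.91 log2 units for TFF1 and 4.32 for BASP1, and of -6.34 or lower for CLDN1. GAGE4 had a negative interaction whose size has no bound, with 3 of the 4 groups below background. ERBB2 and PTK2 had positive interactions of 1.25 ± 0.13 and 1.05 ± 0.13, and EGFR, below background in the untreated arrays, a negative one of -0.38 or lower. Each value is that of the brightest probe. A dimmer PTK2 probe stood at 7.24 in the untreated arrays, 7.17 with PF04554878, 7.05 with lapatinib and 7.16 with both. Camera passed 9 lists for the Y15 interaction and 2 for that of PF04554878, and with an estimated correlation each of these calls was lost (lowest adjusted p = 0.112 and adjusted p = 0.180 with an estimated correlation).

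Y15 and PF04554878 were compared directly at 1 µM and 24 hours. MAGED1 was at least 20.7-fold, TRIP6 at least 14.7-fold and KDELR1 at least 13.1-fold higher in the arrays labelled Y15, and UBB (-3.56 ± 0.17), LAMP3, PCDHB2 and CPE were lower. On their brightest probes, PTK2 was higher by 0.52 ± 0.10 (adjusted p = 0.000325), ERBB2 by 0.56 ± 0.09 and ERBB3 by 0.62 ± 0.14. A dimmer PTK2 probe went the other way, at 7.10 with Y15 and 7.17 with PF04554878. So did a dimmer ERBB3 probe, at 7.18 and 7.47, while another stood at 6.89 and 6.79. PTK2B, the FAK paralog, differed by -0.05 (95% confidence interval -0.24 to 0.14, adjusted p = 0.679). Its brightest probe was dim, at 6.85 with Y15 and 6.90 with PF04554878, and above background on 9 of the 12 arrays. The other PTK2B probes were above background on 2 and 0 arrays. Folds of dim genes are compressed, so this interval does not bound the change in the PTK2B transcript. By limma 5483 genes passed, 2651 higher and 2832 lower. Ribosome biogenesis genes were higher in 15 of 27 cases and lower in 2, the same adjusted over the list alone (adjusted p = 0.00269, and adjusted p = 0.230 with an estimated correlation).

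With lapatinib present, the arrays labelled with Y15 and with PF04554878 differed in 6278 genes, 3135 higher with Y15 and 3143 lower. GAGE4 was at least 103-fold higher with Y15, and TFF1 at least 122-fold and SERPINA3 at least 25.7-fold lower. Mitotic genes were higher in 21 of 30 cases and lower in 2, with PTTG1 at 1.40 ± 0.09 (adjusted p = 4.63e-05, and adjusted p = 0.134 with an estimated correlation), and DNA replication genes higher in 19 of 29 and lower in 4, with RFC4 at 2.70 ± 0.09 (adjusted p = 0.00567, and adjusted p = 0.151 with an estimated correlation), each the same adjusted over the list alone. The p53 targets were lower in 11 of 19 cases and higher in 2, or 14 and 2 adjusted over the list alone, with CDKN1A at -2.85 ± 0.19 and TP53I3 the other way at 4.27 ± 0.09 (adjusted p = 0.0106, and adjusted p = 0.134 with an estimated correlation). NRF2 targets were lower in 10 of 19 and higher in 2 (adjusted p = 0.00889, and adjusted p = 0.151 with an estimated correlation), antigen presentation genes higher in 8 of 17 (adjusted p = 0.0106, and adjusted p = 0.134 with an estimated correlation), and YAP and SRF targets higher in 11 of 23 and lower in 2 (adjusted p = 0.0473, and adjusted p = 0.213 with an estimated correlation), the same adjusted over the list alone. EGFR differed by 0.08 (95% confidence interval -0.11 to 0.27, adjusted p = 0.494). Its probe was dim, at 7.01 with Y15 plus lapatinib and 6.93 with PF04554878 plus lapatinib. Folds there are compressed, so the interval does not bound the change in the EGFR transcript.

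The remaining comparisons, added after seeing the data, set each combination against its FAK inhibitor. In the arrays labelled PF04554878 plus lapatinib, against PF04554878, UGT2B15, a steroid-conjugating enzyme, was higher by 1.43 ± 0.09, CCDC117 by 1.34 ± 0.16 and SERPINA3 by 1.26 ± 0.12. CEACAM6 and TCN1 were at least 3.90-fold and 3.65-fold lower, and NECAB1 and KYNU fell by 2.18 ± 0.17 and 2.16 ± 0.10. In all 1027 genes passed, 474 higher and 553 lower, and ERBB2 rose by 0.40 ± 0.09, a call that ended without PF04554878 replicate 1 or either combination array. DNA replication genes fell in 5 of 29 cases, or 8 adjusted over the list alone (adjusted p = 0.000123, and adjusted p = 0.107 with an estimated correlation), and mitotic genes in 6 of 30, or 9 with 1 rise adjusted over the list alone (adjusted p = 0.000126, and adjusted p = 0.107 with an estimated correlation), with BIRC5 at -0.98 ± 0.10. ER chaperone genes rose in 5 of 16, or 6 adjusted over the list alone (adjusted p = 0.00118, and adjusted p = 0.107 with an estimated correlation), and other receptor tyrosine kinases rose in 4 of 11 and fell in 1, the same adjusted over the list alone, with FGFR4 at 0.86 ± 0.16 (adjusted p = 0.0176, and adjusted p = 0.129 with an estimated correlation). The count was 504 and 584 without PF04554878 replicate 1 or 2, 551 and 420 without PF04554878 plus lapatinib replicate 1 or 2, and 600 after background subtraction.

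The arrays labelled Y15 plus lapatinib and Y15, which lie in different sets, differed in 6279 genes, 3103 higher in the former and 3176 lower, with GAGE4 at least 103-fold higher and TFF1 at least 104-fold lower, and 0 of the 26 lists passed camera, with 5 at an unadjusted p under 0.05, or 1 with an estimated correlation. This profile correlated across genes with that of lapatinib against untreated, with which it shares no arrays, at r = 0.918. The difference between PF04554878 plus lapatinib and PF04554878 correlated with that of lapatinib against untreated at r = -0.0150.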

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

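The tests of cell identity, of a recurring lapatinib response, of RNA quality and of neighbouring genes in the arrays labelled lapatinib were chosen only after the results they bear on had been seen. The values in the next paragraphs are those where the test of an interaction passed. By the labels, the effect of a FAK inhibitor then differed beside lapatinib. For Y15, the pairs with and without lapatinib lie in different sets of arrays. A constant log2 difference between these sets cancels, but a Y15 effect that differs between them cannot be told apart from a joint effect of the drugs. For PF04554878, a difference between sets enters the interaction directly.

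For Y15 by lapatinib, 447 genes passed. The largest positive differences were in SOWAHA (1.31), PLK2 (1.23), PNN (1.18) and RETREG1 (1.13), and the largest negative ones in TFF3 (-2.43), EEF1A2 (-1.47), MACROD1 (-1.33) and HEY2 (-1.32). Ribosome biogenesis genes had a positive median of 0.27 (adjusted p = 0.000194, and adjusted p = 0.112 with an estimated correlation), with DKC1 at 0.85, NCL at 0.54 and NOP56 at 0.55. Mitotic genes had a median of 0.23 (adjusted p = 0.000382, and adjusted p = 0.112 with an estimated correlation), with TTK at 0.61 and CENPE at 0.78. DNA replication genes had a median of 0.15 and xenobiotic genes one of 0.26, with 0 members passing limma's test in either list (adjusted p = 0.0195 and 0.0381, and adjusted p = 0.193 with an estimated correlation in both). Heat shock genes had a median of 0.25 with HSPH1 at 0.77, HSPD1 at 0.56 and BAG3 at 0.53 (adjusted p = 0.0123, and adjusted p = 0.193 with an estimated correlation). Metallothionein and zinc transport genes had a median of 0.10, with MT1F at 0.82, MT1X at 1.11 and SLC39A4 at -0.66 (adjusted p = 0.0298, and adjusted p = 0.193 with an estimated correlation).

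Luminal epithelial genes had a negative median of -0.23 in the Y15 interaction, with XBP1 at -1.09 and PGR at -0.55, against ESR1 at 0.73 (adjusted p = 0.00494, and adjusted p = 0.112 with an estimated correlation). The basal epithelial markers ACTA2 and CDH3 stood at -0.72 (adjusted p = 0.0107) and -0.36 (adjusted p = 0.260). The ATF4 and amino acid list had a median of -0.14, with DDIT4 at -0.89, NUPR1 at -1.03, CBS at -0.63 and ASNS at -0.61 (adjusted p = 0.00408, and adjusted p = 0.211 with an estimated correlation). FOXO targets had a median of -0.15, with YPEL3 at -0.89 and KLF6 at 0.50 (adjusted p = 0.0381, and adjusted p = 0.211 with an estimated correlation).

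For PF04554878 by lapatinib, 5208 genes passed. Fitted differences were 6.23 for TFF1, 4.47 for BASP1, 4.06 for HENMT1 and 3.67 for GFRA1, and -7.31 for GAGE4, -7.03 for GAGE12G, -7.00 for GAGE12J and -6.87 for CLDN1. Except for GFRA1, these genes lay below background in at least 1 of the 4 groups, so the fitted values are not exact sizes. With such groups at the cutoff, TFF1 was bounded at 5.91 or more, BASP1 at 4.32, HENMT1 at 3.81 and CLDN1 at -6.34 or less, and the GAGE genes had no bound. YAP and SRF targets had a median of -0.66, with FHL2 at -4.56, ACTA2 at -2.30, CNN2 at -2.01 and MYL9 fitted at -2.33 with no bound (adjusted p = 0.00503, and adjusted p = 0.263 with an estimated correlation). Antigen presentation genes had a median of -0.58, with HLA-B fitted at -4.00 (-3.66 or less), PSMB8 at -2.04 (-1.79 or less), HLA-F at -1.63 and TAP1 at -1.81 (adjusted p = 0.00488, and adjusted p = 0.180 with an estimated correlation). Among the drug targets, PTK2 stood at 1.05, ERBB2 at 1.25 and EGFR was fitted at -0.66 (-0.38 or less, being below background in the untreated arrays).

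The PF04554878 interaction is another view of the 3 sets of arrays. A lapatinib response that recurs beside PF04554878 is argued against by the correlation across genes of -0.0150 between the lapatinib effects with and without PF04554878, and poorer RNA in a set by 74 genes that were below background on all 4 arrays of a set and over 4-fold above it on all 4 of another, although only 9 and 3 such genes, by direction, separated the untreated and Y15 arrays from the PF04554878 set, where poorer RNA stays open. Cells of different genomes behind the labels may account for part of the sets: medians over runs of 20 neighbouring genes varied 5.45 times as much as in shuffled orders for lapatinib against untreated and 4.03 times as much for PF04554878 against untreated, against at most 2.11 between groups of the same set. The ratios within a set, 2.11, 1.61 and 1.46, also exceeded the highest shuffled ratios, 1.21, 1.21 and 1.18. Neighbouring genes thus moved together within a set too, and a raised ratio alone does not show different genomes. Smaller changes within a set leave less to see in that test. A response to PF04554878 that overrides lapatinib in 1 cell line also stays open, as does a drug effect beneath any difference in cells.

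ESR1 was above background on 12 arrays, although SKBR-3 is known to lack the oestrogen receptor, and RNA from cells other than SKBR-3 is a candidate explanation. Whether ERBB2 itself was low or its probe read low stays open: the other genes of the ERBB2 amplicon had a median 0.691 log2 units above background, but levels of different probes share no scale and no SKBR-3 array served as a reference. Which cells the RNA came from was not determined, and no biological explanation in SKBR-3 was tested.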

How the results depend on the processing

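Background subtraction, the variance trend and the comparisons of each combination with its FAK inhibitor were chosen only after the data had been seen. The filters on dim probes (20044 and 7874 genes) and the variance trend left each of the 13 counts of changed genes within 1.5 times its value. Among named genes called in the main fit or in the alternative, 0 reversed direction under any alternative run. Changes of sign in genes called in neither were not counted. Among named genes, calls were lost in 184 cases on leaving out an array, 56 after background subtraction, 35 with the replicate number as a block and 18 in fits of the compared groups alone. With every probe as a feature, which tests 19922 features, counts were 10049 for lapatinib, 9629 for Y15 plus lapatinib, 10222 for PF04554878 plus lapatinib against lapatinib, 7825 for the PF04554878 interaction, 9588 between the combinations and 9591 for Y15 plus lapatinib against Y15. In fits of the compared groups alone they were 60 for Y15 and 288 for its interaction. Such fits have fewer samples, but this alone does not account for the drops. Counts fell in every comparison that holds the untreated group and rose in every other one. For Y15 plus lapatinib against lapatinib the count rose from 1306 to 1826. The 2 untreated arrays differed with an SD of 0.229 across genes, against 0.137 to 0.162 in the other groups, and the main fit pools these spreads. Background subtraction gave 192 for Y15, 513 for Y15 plus lapatinib against lapatinib, 5 for the Y15 interaction and 600 for PF04554878 plus lapatinib against PF04554878, and the cause was not tested. Leaving out an array gave 136 to 1171 for Y15, 30 to 999 for its interaction, 299 to 620 for Y15 plus lapatinib against lapatinib and 420 to 584 for PF04554878 plus lapatinib against PF04554878, the lone array being taken to vary like the other groups. With an estimated correlation, 2 lists passed for PF04554878 plus lapatinib against untreated and 0 in each other comparison. Same-numbered arrays did not deviate together (r from -0.33 to 0.13 over 10 pairs of groups, median -0.07, 1 over 0.1), so the numbers do not pair the samples. The replicate block gave 356 genes for Y15, 510 for Y15 plus lapatinib against lapatinib, 22 for the Y15 interaction and 1 list for Y15 plus lapatinib against Y15. The block ended 2 list calls, both in comparisons with that group, and added 4. The calls ended were heat shock genes in Y15 plus lapatinib against lapatinib and YAP and SRF targets between the combinations. Not run were the planned normexp correction, median scaling, and the BeadChip as a block, and the detection filter of the raw signals was replaced. Signal over background limits dim genes, whose folds are compressed or bounds.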

Other observations

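The test of a shift shared by the 3 sets was chosen only after the results had been seen. Within each set, 1 pair of groups could be compared without crossing sets: Y15 with untreated, Y15 plus lapatinib with lapatinib, and PF04554878 plus lapatinib with PF04554878. All 3 comparisons called 32 genes higher and 45 lower, against 0.842 and 0.725 for independent lists. The lists are not independent, since the 3 comparisons share the estimate of each gene's spread, and part of the excess may come from this. IER3, an immediate early gene, had a mean change of 1.26, followed by NR2E3 (0.84), VMA21 (0.82), FAM217B (0.80), B3GALNT1 (0.76) and the peroxisomal oxidase ACOX2 (0.74). The Wnt antagonist DKK1 had a mean change of -1.45, SSRP1, a histone chaperone subunit, -1.08, ANAPC13 -0.93, KCNK2 -0.82 and the apoptosis inhibitor BIRC5 -0.71. Of 26 lists tested on the mean of the 3 changes, the luminal epithelial list passed (median 0.11, adjusted p = 0.0454, and adjusted p = 0.301 with an estimated correlation). It did not shift up in all 3: its medians were 0.13 for Y15 against untreated, -0.06 for Y15 plus lapatinib against lapatinib (adjusted p = 0.670) and 0.08 for PF04554878 plus lapatinib against PF04554878 (adjusted p = 0.0605).

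A hypothesis is that 1 treatment or handling difference is common to these 3 comparisons, which share no arrays and have different labels. Changes correlated across genes at r of 0.150, 0.191 and 0.316, while the highest size of r among 24 other pairs of splits of the sets was 0.342, so none of the 3 exceeded it. The third principal component, with 4.05% of the variance, went with a common difference: its scores were 3.39 or more in the untreated, lapatinib and PF04554878 arrays and -6.48 or less in their partners. Whether treatment or handling underlies it cannot be told apart, since the labels give the partners Y15 in 2 sets and lapatinib in the other. The Spearman correlation between mean change and mean level across genes was 0.0551. This cannot decide on a shift that follows intensity, since arrays with nearly equal sorted values leave little room for one.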
